A study of Mus musculus with 12 samples.

How the data were processed

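RNA was measured by sequencing in 12 libraries from mouse thymus, 4 from each of 3 sorted CD4+ populations. Per the labels' protocols, all cells came from CD4-Cre x Foxp3-GFP mice, in which a green fluorescent reporter marks cells that express Foxp3. The populations were Eos+ Tregs, sorted as Foxp3+ cells with Ccr6 and Cxcr4 on the surface, Eos- Tregs, sorted as Foxp3+ cells without Ccr6 and Cxcr4, and Foxp3- conventional T cells (Tconv). Tregs are regulatory T cells, and Eos is the transcription factor encoded by Ikzf4. Per the labels' protocols, cDNA was made from 1 ng of total RNA with a template-switching kit for low input and turned into libraries by tagmentation. This kind of kit does not mark the strand of the RNA.

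The deposited values were expected counts per gene, as RSEM gives them, not scaled for depth or gene length. Per the submitters' processing notes, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 were used with the mm10 genome (GRCm38). Their parameters and the annotation release were not given in the sources used here. All 55450 gene IDs matched the GENCODE M21 annotation, from which positions were taken. Between 9.54% and 10.74% of the 55450 gene values per library, zeros included, were not whole, since RSEM shares out reads that match several genes. Only 17727 to 20148 genes per library held a count after rounding, and the share among nonzero values is higher. Genes in families of similar sequence, such as Ly6c1, Ifit1, Oas2 and Klrb1c, are therefore less certain. Of the 106 genes taken for naming, 28 share exon positions with another annotated gene and 9 with one that reached 5 CPM in some library (Als2cl, Cxcr5, Ebi3, Foxp3, Gpr15, Lef1, Nfkb2, Satb1 and Tnfrsf18). Without strand, reads from such genes cannot be told apart, so these values are uncertain.

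Depth ran from 23.9 to 37.9 M expected counts per library. The 10 most abundant genes took 3.55% to 4.21% of the counts, and mitochondrial genes 0.51% to 1.4%. Counts of replicate libraries differed by more than sampling noise in all 18 pairs within a group (chi-square per degree of freedom 26.1 to 81.4), which does not tell separate samples from repeat libraries of the same sample. The labels do not say whether replicates came from separate animals. Ddx3y, on the Y chromosome, was 120 to 187 CPM in the libraries numbered 1 and 3 and 0 in those numbered 2 and 4. Xist was 38.8 to 150 CPM in numbers 2 and 4 and at most 0.559 in 1 and 3. These values place cells of both sexes in each group and argue against a single animal as the source of all its replicates. They do not part number 1 from 3 or number 2 from 4. P-values measure the spread between these libraries, which may in part be technical.

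Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. The quasi-likelihood F test was used with TMM factors and the filterByExpr filter, in a model with 1 mean per group over all 12 libraries, which kept 15361 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method per comparison, with a threshold of 0.05. Levels are CPM on TMM-scaled totals, as edgeR gives them, and fold changes are those of the edgeR fit. Where a group held no count, 3 counts over the group set a lower bound on the fold, and where it held 1 to 3 counts the ratio has an exact 95% interval. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

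The model, the lists and the other fits listed below were chosen before the data were examined. There were 30 gene lists, 22 of programs and 8 of markers of other cells that a CD4+ thymus gate could hold, with 605 genes in all, of which 574 were measured. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 90 tests. Member counts are given over all tested genes and adjusted over the list alone. Of the 605 genes, 80 stood in 2 or more lists, so the lists are not separate evidence. The Treg identity list shares Tnfrsf4, Tnfrsf18 and Tnfrsf9 with the NF-kB list. It shares Il2ra and Socs2 with the IL-2 list and Cd83 with the early T cell receptor list. Camera was run again with the correlation estimated per list, and 0 of the 48 calls held. Some other splits of the same libraries called as many lists (4, 3 and 7 of 35 splits, the real one included), so the statements on groups rest on their member counts rather than on the list test. The sort markers and Ikzf4 were compared by an exact two-sided permutation test of log2(CPM + 1), whose smallest p over 70 arrangements is 0.029.

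The rule for genes to name took, per comparison, the 10 largest changes in each direction among called genes whose groups did not overlap and whose mean reached 10 CPM, the 5 label genes, and up to 4 members of each list. Predicted genes, receptor variable segments and mitochondrial genes were left out. The text names a subset of these genes, and that subset was picked after their values and their results under the alternatives had been seen. Genes that lost a call when a library was left out were dropped more often than others, so the closing section gives stability over all genes of the rule. Ighm in Eos+ against Eos- Tregs, Ms4a1 and Cd22 fall outside the rule and were chosen after their values were seen. Some of the genes taken for naming are not reported here.

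The labels give replicate numbers, and the library names share an identifier per number. Deviations from the group means correlated at 0.14 to 0.32 across genes in the 12 pairs of libraries with the same number and at -0.23 to 0.07 in other pairs, and 12 of 12 libraries correlated best with their own number. Xist reached 38.8 to 150 CPM with 2 of the numbers (2 and 4), and Y-linked genes were found with the other 2. The numbers were therefore taken to pair the libraries. The main fit, chosen beforehand, does not use the pairing, and a fit with the number as a block is given beside the results it changes.

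The fits chosen beforehand used RLE and upper-quartile factors, no filter and a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom with and without library weights, robust dispersion, a fit of only the groups compared, the replicate block, a test against a 1.5-fold change (glmTreat), unrounded counts, fry for the lists, and each library left out in turn. Fits without the libraries numbered 1, or 1 and 2, and the block with an estimated correlation, were added after seeing the data. The scripts were tested on simulated counts with known changes in 66 or 67 genes per fold, none of them among the least abundant genes. That is a far smaller share of changed genes than was called in the data, so recovery in the data may differ. For Eos+ against Eos- Tregs, 20.9% of 1.5-fold, 68.7% of 2-fold and 89.4% of 4-fold changes were recovered, with 6 of 125 calls false. For Eos+ Tregs against Tconv these were 29.9%, 68.7% and 95.5%, with 2 of 131 calls false. For Eos- Tregs against Tconv they were 26.9%, 65.7% and 92.4%, with 2 of 125 calls false.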

Results

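Gene expression was measured in 3 CD4+ populations sorted from mouse thymus, with 4 libraries per population. Eos+ Tregs held 31.4 to 35 M expected counts per library, Eos- Tregs 23.9 to 35.6 M and Tconv 27.6 to 37.9 M. The series title places the question in Eos and the Tregs that recirculate to the thymus. Levels below are CPM as mean ± SD over 4 libraries (n = 4), and p-values not called otherwise are adjusted p from edgeR. The first principal component (37.1% of variance) separated the 3 groups, and on the second (18%) Eos- Treg replicate 1, at -19.4, lay apart from the other Eos- Treg libraries, at 60.7 to 84.8.

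**Figure D1:**
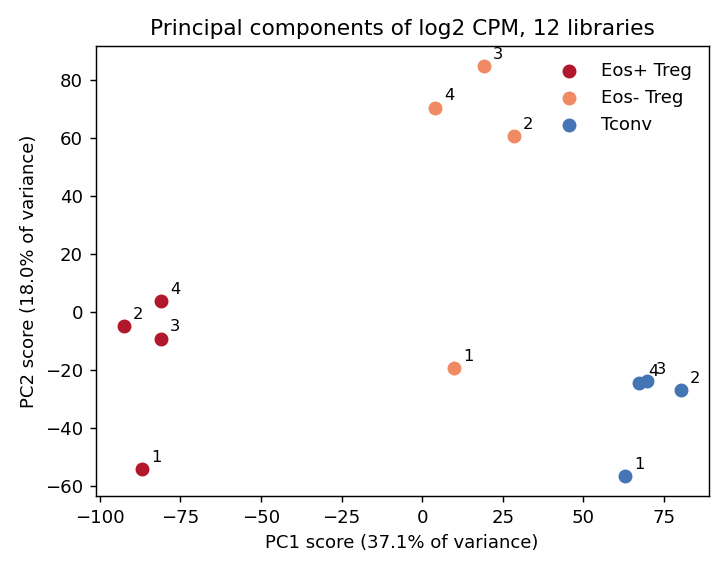
Scores of the 12 libraries on the first 2 principal components of log2 CPM (x axis, PC1, 37.1% of variance, and y axis, PC2, 18% of variance), 1 point per library, coloured by group and numbered by replicate. Eos- Treg replicate 1 sits at a PC2 score of -19.4, and the other 3 Eos- Treg libraries at 60.7 to 84.8.

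The sort markers and Ikzf4, which names the groups but was not sorted on, checked the labels and are not findings. Eos- Tregs were not free of Ikzf4 transcript. Their mean was 6.75-fold that of Tconv, and the mean of Eos+ Tregs was 1.84-fold that of Eos- Tregs. Ikzf4 (ENSMUSG00000002578.17, chromosome 10, 128630843 to 128645991, mm10) stood at 314 ± 17.5 CPM in Eos+ Tregs, 171 ± 12.7 in Eos- Tregs and 25.3 ± 2.22 in Tconv (SD, n = 4), with an exact permutation p of 0.029, the smallest possible, for each pair of groups. Foxp3 (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245) stood at 504 ± 329 and 582 ± 363 CPM in Eos+ and Eos- Tregs against 2.03 ± 1.47 in Tconv. In the libraries numbered 1 it was only 55 CPM in Eos+ Tregs and 53.3 in Eos- Tregs. With limma-voom the Foxp3 difference from Tconv did not pass (adjusted p = 0.0793 and 0.11). Ccr6, a sort marker, stood at 246 ± 15, 14.4 ± 3.92 and 3.27 ± 1.49 CPM. Cxcr4, the other surface marker of the sort, was 39.1 ± 11.3, 28.7 ± 9.25 and 15.2 ± 6.33 CPM, and its levels in Eos+ and Eos- Tregs were not told apart (exact permutation p = 0.26). Against Tconv, the Cxcr4 difference had an exact permutation p of 0.029 in each Treg group, but not when Tconv replicate 2 or 4 was left out for Eos+ Tregs (p = 0.0571 by exact permutation). For Eos- Tregs it was lost without Tconv replicate 2 or any 1 of the 4 Eos- Treg libraries (exact permutation p = 0.0571 to 0.114). The main edgeR fit did not call Cxcr4 in Eos- Tregs against Tconv (adjusted p = 0.0777). It was called with the replicate block, without the libraries numbered 1, with DESeq2 and with library weights in limma-voom. Cd4 was 574 ± 43.2, 635 ± 63.7 and 949 ± 95.2 CPM.

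**Figure D2:**
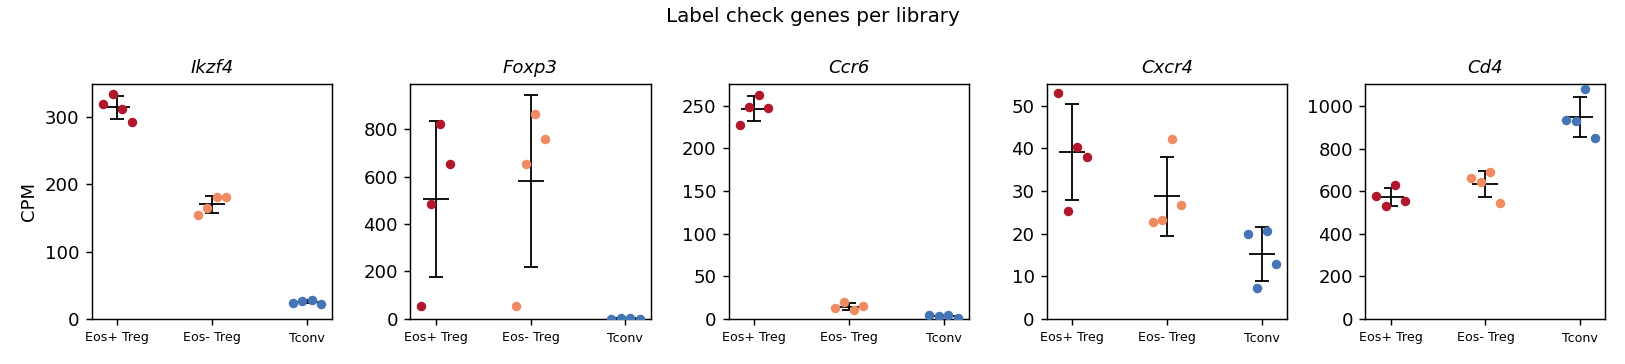
CPM (y axis, from 0) of the 4 sort markers and of Ikzf4 in each library, by group on the x axis, with points for libraries and bars for mean and SD (n = 4). Foxp3 is at 55 and 53.3 CPM in the Treg libraries numbered 1, and the means of Ikzf4 are 314, 171 and 25.3 CPM.

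Eos+ Tregs differed from Eos- Tregs by higher transcripts of 22 of 30 effector Treg genes, 19 of 28 migration and S100 genes and 11 of 20 glycolysis genes, and by lower transcripts of 15 of 22 genes of naive T cells and 17 of 30 interferon-stimulated genes. Nrp1 (chromosome 8, 128358604 to 128503363), a semaphorin and VEGF coreceptor, was 657 ± 55.3 against 131 ± 19.9 CPM, 5.02-fold higher (adjusted p = 1.15e-05). Il1r2, a decoy receptor for interleukin-1, was 46.7-fold higher at 300 ± 57.4 against 6.43 ± 4.15 CPM (adjusted p = 2.18e-05). Satb1 (chromosome 17, 51736187 to 51833290), a chromatin organiser of thymocytes, was 415 ± 90 against 1470 ± 208 CPM, 3.54-fold lower (adjusted p = 1.88e-05). In all, 2500 of 15361 genes changed, 1509 of them higher and 991 lower, at 4459 with an unadjusted p under 0.05. Of these, 880 were more than 2-fold higher and 260 more than 2-fold lower. The groups did not overlap in 20% of genes, where chance gives 2.86%. The replicate block gave 3498 changed genes. Leaving out the 6 libraries numbered 1 and 2 left 972 changed genes, and a test against a 1.5-fold change gave 778.

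Among the largest increases in Eos+ Tregs was that of Muc16, a membrane mucin (ENSMUSG00000109564.1, chromosome 9, 18495455 to 18674530), at 10.2 ± 2.1 CPM and without a count in Eos- Tregs, at least 418-fold higher. Tff1, a trefoil peptide of the stomach lining (chromosome 17, 31161395 to 31165277), was 42.8 ± 13.7 against 0.279 ± 0.153 CPM (adjusted p = 3.25e-06). Tg, the thyroglobulin gene, was 31.9 ± 10.1 against 0.824 ± 0.494 CPM, Pcsk1, a prohormone convertase, 12.6 ± 5.17 against 0.0936 ± 0.169, and Sspo, which encodes SCO-spondin, 15.1 ± 7.02 against 0.395 ± 0.744. The Pcsk1 level in Eos- Tregs came mostly from replicate 3 (0.346 CPM, and at most 0.0287 in the others) and that of Sspo from replicate 2 (1.51 CPM, and at most 0.0691 in the others). Their log2 changes were 7.04 and 5.18, and 9.76 and 9.14 without that library. Ptpn5, a tyrosine phosphatase, was 109-fold higher at 81.1 ± 13.2 CPM. Among the largest decreases were Ly6c1 (5.28 ± 2.83 against 30.9 ± 12.1 CPM), Igfbp4 (19.6 ± 7.13 against 100 ± 36.4), Ampd1 (6.96-fold lower, 1.79 ± 0.729 in Eos+ Tregs), Pde3b (11.7 ± 3.99 against 53.2 ± 21.5) and Tgfbr3 (13 ± 3.69 against 55.9 ± 9.88).

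Of the 30 effector and tissue Treg genes measured, 22 rose, 0 fell and 8 did not pass, and 25 rose when adjusted over the list alone. Tigit, an inhibitory receptor, was 18-fold higher, Itgae, the integrin chain CD103, 10.4-fold, Ebi3, a cytokine subunit, 23.2-fold, and Prdm1, the gene of Blimp-1, 4.94-fold. The camera call was adjusted p = 6.63e-15, and adjusted p = 0.0985 with an estimated correlation. Among 25 Treg identity genes, which include Foxp3 and Ikzf4, 15 rose and 2 fell (17 and 2 adjusted over the list alone, and adjusted p = 0.2 with an estimated correlation). Cd83 was 564 ± 65.1 against 141 ± 14.3 CPM, while Il2ra (546 ± 105 against 490 ± 93.7) did not pass. Of 28 migration, adhesion and S100 genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone, adjusted p = 0.151 with an estimated correlation), among them Ahnak (287 ± 47.2 against 41 ± 12.7 CPM), S100a4 and S100a6. Itgb1 and Itgb8 were 3.52-fold and 3.26-fold higher and Itgb3 3.6-fold lower among 23 integrins and adhesion receptors, of which 9 rose and 7 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.376).

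Receptor and cytokine genes also differed. Of 27 coinhibitory and costimulatory receptors, 13 rose and 2 fell (14 and 3 adjusted over the list alone, adjusted p = 0.131 with an estimated correlation), with Cd80 11.4-fold and Lag3 4.14-fold higher. Of 25 chemokine and receptor genes, which include the sort markers Ccr6 and Cxcr4, 9 rose and 3 fell (10 and 4 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation). Gpr15, a homing receptor, was 52.2 ± 8.31 against 3 ± 0.778 CPM, Ccl5 37.4 ± 9.49 against 2.84 ± 1.41 and Cxcr5 70.2 ± 19.7 against 7.53 ± 2.07. Of 23 helper lineage genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation), such as Il18r1 at 6.16-fold and Rora at 4.07-fold. Among 27 NF-kB genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation), with Icam1 and Nfkb2 higher by 1.97-fold and 1.65-fold. That list's call was also lost without Eos+ Treg replicate 2, 3 or 4, without Eos- Treg replicate 1 or 2 (adjusted p = 0.0547 to 0.214) and without the libraries numbered 1 (adjusted p = 0.051).

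Genes of naive and resting T cells moved the other way, with 15 of 22 lower and 1 higher (16 and 1 adjusted over the list alone, adjusted p = 0.091 with an estimated correlation). Lef1, a transcription factor of naive T cells, was 303 ± 36.4 against 668 ± 88 CPM, and Als2cl was 3.45-fold and Bcl2, a survival factor, 2.05-fold lower. Of 22 genes of medullary maturation, 12 fell and 2 rose (13 and 2 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation), with Tox2 15.5-fold higher (log2 change 3.95, and 5.04 without Eos- Treg replicate 1). Itm2a was 2.25-fold lower, a call that was lost without the libraries numbered 1 (adjusted p = 0.0661). Of 30 interferon-stimulated genes, 17 fell and 0 rose (23 and 0 adjusted over the list alone, adjusted p = 0.301 with an estimated correlation), among them Oas2 (10.5 ± 4.4 against 36.6 ± 7.87 CPM), Zbp1 (137 ± 35 against 298 ± 52) and Ifit1 (147 ± 17 against 295 ± 27.3). Among 29 Ikaros family and Eos or Foxp3 partner genes, 8 fell and 4 rose (8 and 5 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation), including Ikzf1, 1.86-fold lower. The call of that list was lost with the replicate block (adjusted p = 0.0511), without the libraries numbered 1 (adjusted p = 0.0856), and without Eos+ Treg replicate 1 or 2 or Eos- Treg replicate 1 or 3 (adjusted p = 0.0506 to 0.0744).

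Of 20 glycolysis genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.091 with an estimated correlation). Tpi1 was 3.27-fold and Pgam1 1.94-fold higher, Hif1a, which drives glycolytic genes, 1.89-fold higher, and Pdk1 1.84-fold lower. The 29 oxidative phosphorylation, 21 cholesterol synthesis and 30 ribosomal protein genes held 0 called members, adjusted over all genes or over the list alone. Camera called the ribosomal list lower (adjusted p = 0.0426, and adjusted p = 0.928 with an estimated correlation), which was lost without Eos+ Treg replicate 2 or 3 or Eos- Treg replicate 4 (adjusted p = 0.263 to 0.402). Cell cycle genes were called higher as lists, but only 1 of 26 S phase genes (Mcm6, 1.72-fold) rose, with 1 lower, and 1 of 26 G2 and M phase genes (Cks2, 2.43-fold), in each case also when adjusted over the list alone. Their adjusted p was 0.798 and 0.783 with an estimated correlation. The S phase call was lost without Eos+ Treg replicate 1 or Eos- Treg replicate 3 or 4 (adjusted p = 0.0761 to 0.12), and the G2 and M phase call without Eos- Treg replicate 3 (adjusted p = 0.0773). Mki67 was 50.4, 18.2, 38.6 and 43.3 CPM in Eos+ Treg replicates 1 to 4 and 43.9, 18.9, 2.59 and 5.92 in Eos- Treg replicates 1 to 4. The mean log2 CPM of the G2 and M phase genes was 4.83, 3.35, 4.05 and 3.99 against 4.69, 3.41, 1.13 and 1.95 in the same order. Among 23 apoptosis regulators 6 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.79), with Pmaip1 4.27-fold higher and Bcl2l11 2.4-fold lower. Of 26 IL-2 and STAT5 response genes, 7 rose and 4 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.409), with Tnfrsf8 21.1-fold higher. The 29 early T cell receptor genes had 7 higher, Irf4 among them at 1.88-fold, and 2 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.338), and the 18 heat shock genes 2 higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.692).

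Some markers of other cells also differed. Over all tested genes, 16.3% were called in this comparison, 1509 of 15361 higher and 991 lower. Of 15 B cell markers, 5 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 0.327 with an estimated correlation). Ighm, the immunoglobulin mu constant region (chromosome 12, 113418558 to 113422730), was 1520 ± 138 against 279 ± 118 CPM, with Ighd and Cd79b 16.2-fold and 7.1-fold higher. Without Eos- Treg replicate 1 the log2 change rose from 4.02 to 4.83 for Ighd, from 2.83 to 3.44 for Cd79b, from 2.78 to 3.66 for Cd79a and from 3.01 to 3.92 for Cd22. Cd79a (14 ± 10.8 against 2.07 ± 2 CPM, adjusted p = 0.0332) lost its call with limma-voom (adjusted p = 0.0684) and without Eos+ Treg replicate 1 or 2 or Eos- Treg replicate 2, 3 or 4 (adjusted p = 0.0704 to 0.0964). Ms4a1 (9.77 ± 6.11 against 0.768 ± 1.54) and Cd22 (8.55 ± 6.13 against 1.07 ± 1.31) did not pass. They did pass without Eos- Treg replicate 1 (adjusted p = 0.000382 and 0.0429), the only Eos- Treg library with Ms4a1 counts (3.07 CPM). Ms4a1 also passed with the replicate block (adjusted p = 0.0111), without the libraries numbered 1 (adjusted p = 0.00147) and, like Cd22, with limma-voom (adjusted p = 0.0413 and 0.0368). Of 11 markers of innate lymphoid and tissue inducer cells, which include Ccr6 and Nrp1, 6 rose (6 adjusted over the list alone, adjusted p = 0.088 with an estimated correlation). Of the 13 genes fixed for that list, 9 also stood in other lists. Of 19 dendritic cell and macrophage markers 3 rose (3 adjusted over the list alone, adjusted p = 0.682 with an estimated correlation), with Ccr2 4.94-fold higher (log2 change 2.3, and 3.04 without Eos- Treg replicate 1). The call of that list was lost without Eos- Treg replicate 3 (adjusted p = 0.0623). Of 11 epithelial and stromal markers, 2 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.465), with Epcam 2.39-fold higher and Pecam1 1.97-fold lower. Aire was 0.675 to 2.47 CPM in the Eos+ Treg libraries and at most 0.0691 in the Eos- Treg libraries. The 22 double-positive thymocyte markers had 2 lower members (camera adjusted p = 0.397, and 0.0447 without Eos+ Treg replicate 1). The 14 CD8, NK and cytotoxic markers had 2 higher (camera adjusted p = 0.79), and the 9 gamma-delta and NKT and 9 erythroid and granulocyte markers 0 called (camera adjusted p = 0.877 and 0.892). The CD8 and NK list had a median log2 change of -0.41 and a mean of -0.02, where camera's direction was up.

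**Figure D3:**
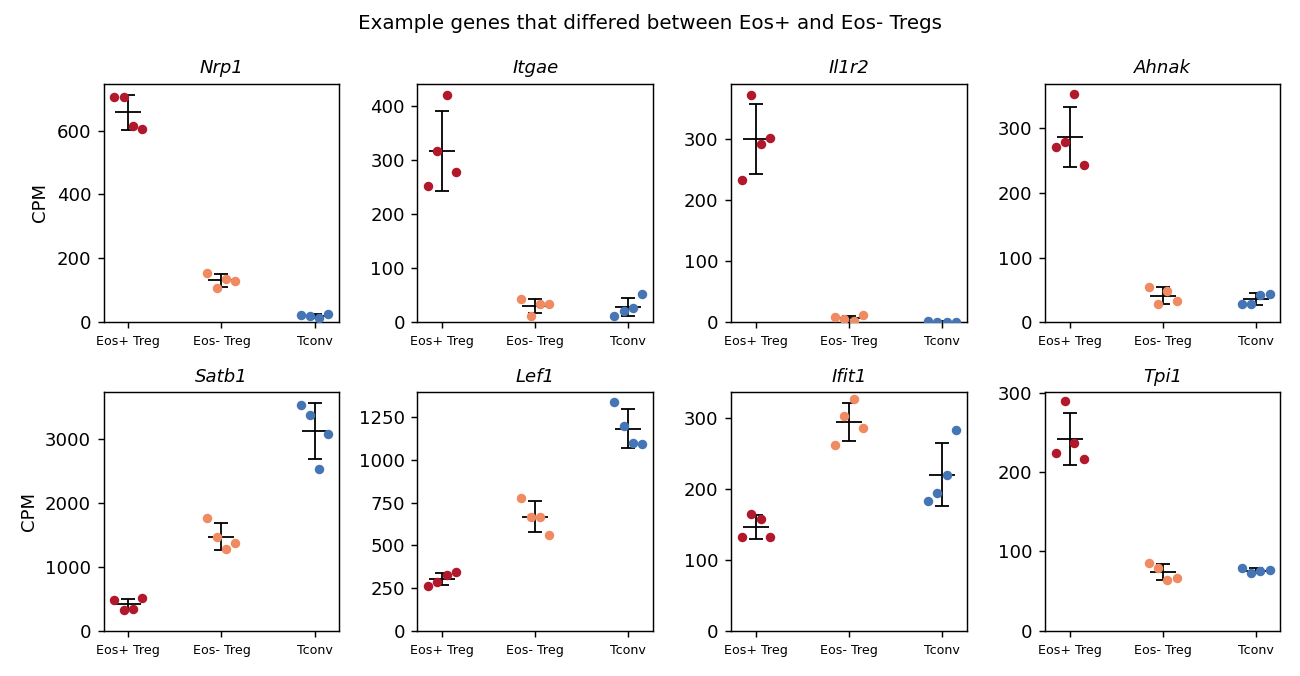
CPM (y axis, from 0) of 8 named genes in each library, by group on the x axis, with points for libraries and bars for mean and SD (n = 4). Nrp1, Itgae, Il1r2, Ahnak and Tpi1 are higher and Satb1, Lef1 and Ifit1 lower in Eos+ than in Eos- Tregs, with Nrp1 at 657 against 131 CPM and Satb1 at 415 against 1470 CPM.

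Against Tconv, Eos+ Tregs had higher transcripts of 24 of 25 Treg identity genes, 20 of 30 effector Treg genes, 20 of 27 NF-kB genes and 21 of 28 migration and S100 genes. Lrrc32, which encodes GARP, a surface anchor of latent TGF-beta (chromosome 7, 98489283 to 98502181), was 474 ± 81.5 against 3.12 ± 0.722 CPM, 151-fold higher (adjusted p = 9.12e-09). Il1r2 was 300 ± 57.4 against 0.68 ± 0.454 CPM, and Klrg1, an inhibitory receptor of effector cells, 22 ± 9.48 against 0.041 ± 0.0483 (log2 change 9, and 9.79 without Tconv replicate 3). Satb1 was 7.53-fold and Igfbp4 25.1-fold lower. In all, 4655 genes changed, 2661 of them higher and 1994 lower, at 6086 with an unadjusted p under 0.05. More than 2-fold changes numbered 1527 higher and 648 lower, and the groups did not overlap in 33.1% of genes. The count of changed genes was 5571 with the replicate block, 2352 without the 6 libraries numbered 1 and 2 and 1854 in a test against a 1.5-fold change.

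The largest increases included Tff1, with 5837 counts against 1 in Tconv (a ratio of 5570, exact 95% interval 1000 to 220000), and that count lay in Tconv replicate 4 (log2 change 11.85, and 13.41 without it). Dkk3, a secreted Wnt modulator, was at least 908-fold and Cavin1, of caveolae, at least 682-fold higher, with 0 counts in Tconv. Hdac9, a histone deacetylase, was 55.3 ± 15.8 against 0.2 ± 0.19 CPM (log2 change 8.01, and 8.80 without Tconv replicate 4). Among the largest decreases were Slc15a1, a peptide transporter (0.248 ± 0.189 against 20.1 ± 5.9 CPM), Chl1 (1.25 ± 0.76 against 49.1 ± 13.1) and Adgrg3 (1.6 ± 0.761 against 53.1 ± 7.32).

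Of the 25 Treg identity genes, 24 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.067 with an estimated correlation). Il2ra, the high-affinity interleukin-2 receptor chain, was 32.5-fold, Ctla4 29.6-fold and Ikzf2, the gene of Helios, 9.93-fold higher. Of 30 effector Treg genes, 20 rose and 3 fell (21 and 3 adjusted over the list alone, adjusted p = 0.2 with an estimated correlation), with Tigit 84.2-fold and Ebi3 100-fold higher. The log2 change of Tigit was 6.4, and 7.15 without Tconv replicate 4, and that of Ebi3 6.65, and 7.37 without Tconv replicate 1. Of 28 migration and S100 genes, 21 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.2 with an estimated correlation), such as Ahnak (8.03-fold), Capg (7.7-fold) and Nt5e (14-fold). Among 27 NF-kB genes, 20 rose and 1 fell, as when adjusted over the list alone (adjusted p = 0.2 with an estimated correlation), with Traf1 4.09-fold and the receptors Tnfrsf4, Tnfrsf18 and Tnfrsf1b 9.62-fold, 5.31-fold and 4.92-fold higher. Of 26 IL-2 and STAT5 response genes, 15 rose and 5 fell (18 and 7 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation), Socs2 being 21.8-fold higher. Of 27 coinhibitory and costimulatory receptors, 18 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.067 with an estimated correlation), while Cd40lg, the ligand of CD40, was 7.35-fold lower. Among 29 early T cell receptor genes 13 rose and 1 fell (13 and 2 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation), and Cd83 was 52.1-fold higher. The 20 glycolysis genes had 12 higher, such as Slc16a3 at 7.39-fold, and 2 lower (13 and 4 adjusted over the list alone, adjusted p = 0.2 with an estimated correlation). The 23 integrins and adhesion receptors had 13 higher and 6 lower (14 and 6 adjusted over the list alone, adjusted p = 0.237 with an estimated correlation). Of 23 apoptosis regulators 13 rose and 5 fell, as when adjusted over the list alone (adjusted p = 0.397 with an estimated correlation), a call lost with a stricter count filter (adjusted p = 0.0542) and without Eos+ Treg replicate 4 (adjusted p = 0.0657).

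Naive and resting T cell genes had 11 lower and 1 higher of 22, as when adjusted over the list alone (adjusted p = 0.2 with an estimated correlation), Lef1 being 3.9-fold lower. Medullary maturation genes had 7 higher and 3 lower of 22 (9 and 3 adjusted over the list alone, camera adjusted p = 0.592), and Itm2a was 7.19-fold lower. Of 30 interferon-stimulated genes, 11 fell and 4 rose (11 and 5 adjusted over the list alone). Camera did not call that list (adjusted p = 0.0559), but did with the replicate block (adjusted p = 0.0319) and without Tconv replicate 1 or 2 or Eos+ Treg replicate 3 or 4 (adjusted p = 0.00892 to 0.0367). Of 25 chemokine and receptor genes 12 rose, with Gpr15 242-fold and Cxcr5 25.4-fold higher, and 4 fell, as when adjusted over the list alone. The log2 change of Gpr15 was 7.92, and 8.77 without Tconv replicate 3. Camera's adjusted p was 0.0543, and 0.024 to 0.0486 without Eos+ Treg replicate 1, 2 or 4 or Tconv replicate 3 or 4. Helper lineage genes had 8 higher and 3 lower of 23 (camera adjusted p = 0.325), and Ikaros family and partner genes 6 higher and 11 lower of 29 (camera adjusted p = 0.183), with a mean log2 change of 0.19 against a median of -0.23. Heat shock genes had 3 higher and 1 lower (camera adjusted p = 0.879), with a mean of 0.08 against a median of -0.14 and a direction down in camera and up in fry.

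Some markers of other cells were called here as well. Over all tested genes, 30.3% were called in this comparison, 2661 of 15361 higher and 1994 lower. A list with a similar share of called members does not stand out from other genes. Of 22 double-positive thymocyte markers 6 fell and 0 rose, as when adjusted over the list alone (adjusted p = 0.734 with an estimated correlation), with Ccr9 12.8-fold (log2 change -3.68, and -4.33 without Eos+ Treg replicate 1) and Sox4 3.68-fold lower. The call of that list was lost without Tconv replicate 1 or Eos+ Treg replicate 3 or 4 (adjusted p = 0.0522 to 0.0602). Of 9 gamma-delta and NKT markers 4 fell, as when adjusted over the list alone (adjusted p = 0.585 with an estimated correlation), among them Zbtb16, the gene of PLZF (0.0364 ± 0.0729 against 5.62 ± 2.66 CPM), and Klrb1c, the gene of NK1.1 (1.88 ± 1.95 against 51.8 ± 33.3). Among Eos+ Tregs only replicate 3 held Zbtb16 counts (0.146 CPM), and the log2 change was -7.11, and -10.50 without it. That of Klrb1c was -4.79, and -5.82 without Eos+ Treg replicate 1. CD8, NK and cytotoxic markers had 5 lower and 1 higher of 14 (camera adjusted p = 0.0865, with the replicate block 0.0476, and 0.0279 to 0.0425 without Tconv replicate 2 or Eos+ Treg replicate 1 or 4). Innate lymphoid markers had 6 higher and 1 lower of 11 (7 and 1 adjusted over the list alone, adjusted p = 0.091 with an estimated correlation). B cell markers had 3 higher of 15, as when adjusted over the list alone (adjusted p = 0.72 with an estimated correlation), a call lost without Eos+ Treg replicate 1 or 2 or Tconv replicate 4 (adjusted p = 0.0584 to 0.128). Epithelial and stromal markers had 3 higher and 2 lower of 11 (camera adjusted p = 0.706, median -0.19 and mean 0.47), and erythroid markers 0 higher and 1 lower of 9 (camera adjusted p = 0.811, median 0.5, direction down).

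Against Tconv, Eos- Tregs had higher transcripts of 20 of 25 Treg identity genes, 20 of 27 NF-kB genes and 13 of 26 IL-2 response genes, and also of S1pr1, the receptor for exit from the thymus. Lrrc32 was 261 ± 83.4 against 3.12 ± 0.722 CPM, 83.2-fold higher (adjusted p = 5.15e-08). S1pr1 was 713 ± 50.8 against 319 ± 34.2 CPM, 2.24-fold higher (adjusted p = 0.000166). Il7r, an interleukin-7 receptor chain, was 117 ± 79.4 against 408 ± 89.1 CPM, 3.5-fold lower (adjusted p = 0.00679). In all, 2249 genes changed, 1345 of them higher and 904 lower, at 4250 with an unadjusted p under 0.05. More than 2-fold changes numbered 577 higher and 277 lower, and the groups did not overlap in 20.1% of genes. The count of lower genes was 1564 with the replicate block, 599 without Tconv replicate 1, 585 without Tconv replicate 2 and 549 without Eos- Treg replicate 4. All changed genes numbered 3300 with the replicate block, 1401 without the 6 libraries numbered 1 and 2, and 513 in a test against a 1.5-fold change.

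Besides Lrrc32, the largest increases included those of Ntn4, of the netrin family (20 ± 2.22 against 0.394 ± 0.243 CPM), Itgb8, an integrin chain that activates TGF-beta (14.8 ± 2.12 against 0.43 ± 0.192), Il2ra (29.2-fold), Syp, the synaptophysin gene (20.3 ± 3.83 against 0.835 ± 0.275, chromosome X, 7638471 to 7653256), and Rln3 (59 ± 9.28 against 2.59 ± 0.704). Among the largest decreases were Slc15a1 (9.27-fold, log2 change -3.21, and -4.10 without Eos- Treg replicate 1), Adgrg5 (8.49-fold) and Qpct (7.65-fold). So was Gzmb, a granzyme (4.89 ± 3.21 against 38.1 ± 24.1 CPM). In Tconv, Gzmb was 73.1 CPM in replicate 4 and 21.9 to 34.9 in the others. Klrb1c was also highest there, at 98.4 CPM against 20.9 to 50.6, as were Zbtb16, Adgrg5, Qpct and Tbx21. Whether NKT cells among Tconv contributed to these decreases was not tested. Of 25 Treg identity genes, 20 rose and 2 fell (21 and 3 adjusted over the list alone, adjusted p = 0.067 with an estimated correlation), with Ctla4 20-fold and Ikzf2 6.47-fold higher. Of 27 NF-kB genes 20 rose and 0 fell (22 and 0 adjusted over the list alone, adjusted p = 0.151 with an estimated correlation), among them Rel (3.15-fold), Tnfrsf4 (6.46-fold), Tnfrsf18 (4.25-fold) and Tnfrsf9 (3.91-fold). Of 26 IL-2 and STAT5 response genes 13 rose and 1 fell (15 and 2 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), with Cish and Socs2, feedback inhibitors of cytokine signalling, 7.16-fold and 10.1-fold higher. Of 27 coinhibitory and costimulatory receptors 15 rose and 3 fell (15 and 5 adjusted over the list alone, adjusted p = 0.091 with an estimated correlation). Early T cell receptor genes had 9 higher and 0 lower of 29 (11 and 1 adjusted over the list alone, adjusted p = 0.415 with an estimated correlation), with Cd83 13-fold higher. Medullary maturation genes had 12 higher and 5 lower of 22 (13 and 5 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation). Of 23 apoptosis regulators 4 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.338 with an estimated correlation). Integrins and adhesion receptors had 9 higher and 2 lower of 23 (10 and 4 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation), a call lost without Eos- Treg replicate 1 (adjusted p = 0.0612) and without the libraries numbered 1 (adjusted p = 0.0632).

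Interferon-stimulated genes had 12 higher and 1 lower of 30 (13 and 1 adjusted over the list alone, adjusted p = 0.645 with an estimated correlation), with Usp18 1.72-fold higher and Oas2 2.45-fold lower. The cell cycle lists were called lower, but 2 of 26 S phase genes fell (0 adjusted over the list alone, adjusted p = 0.59 with an estimated correlation), and 1 of 26 G2 and M phase genes rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.65 with an estimated correlation). Naive T cell genes went both ways, 7 higher and 7 lower of 22 (camera adjusted p = 0.921, mean -0.04 and median 0.2, up in camera and down in fry), with Igfbp4 4.91-fold lower. Effector Treg genes had 10 higher and 7 lower of 30 (camera adjusted p = 0.561), and migration genes 8 higher and 4 lower of 28 (camera adjusted p = 0.752, mean -0.02 and median 0.04). Helper lineage genes had 4 higher and 3 lower of 23, Tbx21 being 4.74-fold lower (log2 change -2.25, and -2.98 without Eos- Treg replicate 1). Camera's adjusted p for that list was 0.13, and 0.0205 without Eos- Treg replicate 1. Lists with a mean and median of opposite sign were also chemokines (mean 0.04, median -0.54, camera adjusted p = 0.752), glycolysis (0.05 and -0.09, camera adjusted p = 0.752) and the Ikaros family and partner genes (0.33 and -0.17, camera adjusted p = 0.752, up in fry).

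Over all tested genes, 14.6% were called in Eos- Tregs against Tconv, 1345 of 15361 higher and 904 lower. Marker lists with a similar share of called members do not stand out from other genes. Among markers of other cells, 4 of 22 double-positive thymocyte markers fell, as when adjusted over the list alone (adjusted p = 0.72 with an estimated correlation). That list's call was lost without Tconv replicate 1 or 2 or Eos- Treg replicate 3 or 4 (adjusted p = 0.0518 to 0.123). Gamma-delta and NKT markers had 2 lower of 9, as when adjusted over the list alone (adjusted p = 0.338 with an estimated correlation), with Zbtb16 at 0.226 ± 0.21 against 5.62 ± 2.66 CPM. CD8, NK and cytotoxic markers had 1 lower of 14 (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). Klrb1c was 4.76 ± 5.35 against 51.8 ± 33.3 CPM, a call lost without Tconv replicate 4 (adjusted p = 0.0528). Its log2 change was -3.46, and -4.52 without Eos- Treg replicate 1. B cell markers had 1 lower of 15, as when adjusted over the list alone (adjusted p = 0.703 with an estimated correlation), a call lost without Eos- Treg replicate 3 (adjusted p = 0.0603). Innate lymphoid and tissue inducer markers had 5 higher and 2 lower of 11 (5 and 4 adjusted over the list alone, camera adjusted p = 0.114, fry adjusted p = 0.000134). Epithelial and stromal markers had 1 higher of 11 (camera adjusted p = 0.877) and erythroid markers 1 lower of 9 (camera adjusted p = 0.667). Dendritic cell and macrophage markers had 0 called of 19 (camera adjusted p = 0.0884, with the replicate block 0.0351, and 0.00176 and 0.0205 without Eos- Treg replicate 1 or Tconv replicate 2).

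**Figure D4:**
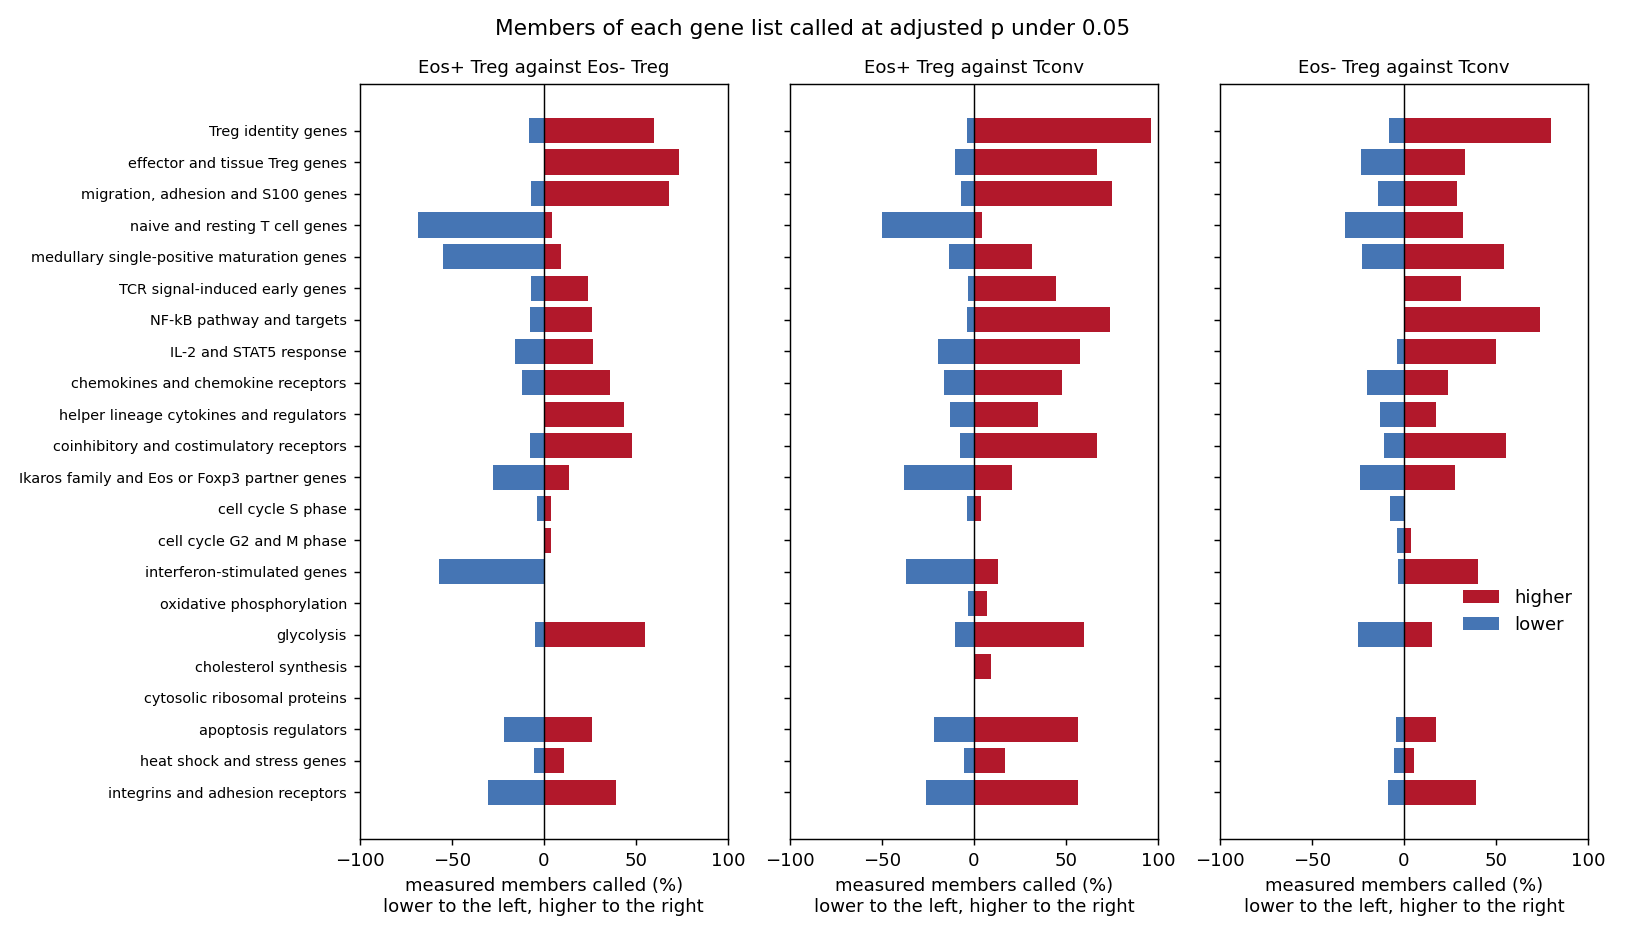
Share of the measured members of each of the 22 program lists (percent, x axis) called higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in the 3 comparisons. Of the Treg identity genes, 15, 24 and 20 of 25 were higher, and of the interferon-stimulated genes 17 of 30 were lower in Eos+ than in Eos- Tregs.

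Both Treg groups were compared with the same Tconv libraries, and 1674 genes changed in the same direction in both, 1069 higher and 605 lower, while 36 changed in opposite directions. Lrrc32, Il2ra, Ctla4 and Ikzf2 were among the shared higher genes. Independent lists of these sizes would share 233 higher and 117.3 lower genes, a figure that takes no account of the shared Tconv libraries. In 20 simulations, with the libraries of all 3 groups drawn at the Tconv means, 0 genes were shared. No gene differed between the simulated groups, so almost none could be called, and that 0 decides nothing on sharing. The covariance of the log2 fold changes was 0.944 (r = 0.64 across genes, which are not independent replicates) against 0.184 (r = 0.5) in the simulations, a difference of 0.76. With the Tconv libraries split 2 against 2, a median of 883.5 genes was shared (842 to 948 over 6 splits), with a covariance of 0.825 to 0.962. Of the 1069 shared higher genes, 309 were also higher and 37 lower in Eos+ than in Eos- Tregs, and 723 did not differ past the threshold. Of the 605 shared lower genes, 144 were lower still in Eos+ Tregs, 6 were higher and 455 did not differ past the threshold.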

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

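The tests that weigh explanations for Foxp3, for 5 genes high in Eos+ Tregs and for the B cell genes were chosen only after those results were seen, and the comparisons with Tconv libraries only after the first B cell tests had been seen.

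Among 237 groups of 4 libraries over the genes taken for naming, 16 (6.8%) held a library far from the others, 7 of them in libraries numbered 1; chance gives about 1 in 20 groups. Values are in CPM, with the range of the other 3 libraries. Low values were Foxp3 in Eos- Treg replicate 1 (53.3 against 653 to 862), Tff1 in Eos+ Treg replicate 1 (22.4 against 47.6 to 52), Pmaip1 in Eos+ Treg replicate 1 (22.3 against 52.3 to 60.3), Tnfrsf4 in Eos+ Treg replicate 1 (1260 against 1380 to 1400) and Hif1a in Eos- Treg replicate 1 (244 against 276 to 279). Also low were Ikzf1 in Eos+ Treg replicate 2 (96.3 against 128 to 134), S100a4 in Eos- Treg replicate 2 (0.826 against 2.08 to 2.35), Slc16a3 in Tconv replicate 3 (4.29 against 5.75 to 5.99) and Ccr6 in Tconv replicate 4 (1.08 against 3.62 to 4.22). High values were Cd83 in Tconv replicate 1 (19.7 against 7.13 to 8.25), Ms4a1 in Eos- Treg replicate 1 (3.07 against 0), Ampd1 in Eos+ Treg replicate 3 (2.89 against 1.41 to 1.44), Tnfrsf18 in Tconv replicate 4 (304 against 202 to 207) and Tnfrsf4 in Eos- Treg replicate 4 (1120 against 825 to 849). Near the floor, Zbtb16 was 0.146 in Eos+ Treg replicate 3 and Tff1 0.0263 in Tconv replicate 4, with 0 in the others.

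Foxp3 was low in both Treg libraries numbered 1, with log2 ratios to the other numbers of -3.54 in Eos+ and -3.82 in Eos- Tregs. Fewer Tregs among those cells would lower the other identity genes as well, but over 19 of them the median log2 ratio was -0.04 (SD 0.3) in Eos+ and 0.01 (SD 0.43) in Eos- Tregs, which argues against that explanation. Genes within 100 kb of Foxp3 (5, Syp among them) had medians of -0.03 and -0.22, so the fall may lie at the Foxp3 gene or its transcript in cells of that number. Other differences specific to number 1 stay open, and no biological explanation was tested.

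Muc16, Tff1, Pcsk1, Tg and Sspo, 5 genes picked after their values were seen and not a list fixed beforehand, were high in Eos+ Tregs. Carried-over thymic epithelial cells would bring keratins, but the highest level of Krt5, Krt8 or Krt14 in an Eos+ Treg library was 1.1 CPM. Tff1 was at least 22.4 CPM there, which argues against keratin-rich epithelial cells. Aire and Epcam went the other way. Aire, a regulator of tissue-restricted genes in medullary epithelium, was 1.13, 2.47, 2.04 and 0.675 CPM in the 4 Eos+ Treg libraries. It was at most 0.0691 CPM in Eos- Tregs and 0.883 in Tconv. Epcam, an epithelial marker, was 22.4 to 36.3 CPM in Eos+ Tregs against 10.1 to 15.1 in Eos- Tregs. It was also 6.28 to 7.65 CPM in Tconv, where Krt5, Krt8 and Krt14 were at most 0.447 CPM. Presence of Epcam alone therefore does not show epithelial cells. The epithelial and stromal list was called higher by fry (adjusted p = 0.0279) but not by camera (adjusted p = 0.465). For B cells, the median log2 ratio of the 5 genes between the Eos+ Treg libraries with the least and the most B cell marker was 0.64 (SD 0.93). For 8 markers it was -1.59 (SD 1.71). That comparison rests on a single pair of libraries and its gap is close to the spread between genes, so it does not decide on B cells. In 6 pairs of an Eos+ Treg library (replicates 3 and 4) with a Tconv library that held more B cell marker, the 5 genes were higher in Eos+ Tregs by a median log2 ratio of 4.14 to 6.94, but these genes were picked for being high in Eos+ Tregs, so this ratio decides nothing on B cells. Expression by the Eos+ Tregs themselves may remain as a hypothesis, as may carry-over of B cells. Carry-over of other cells that express Aire also stays open and was not tested, although a complete sort for CD4+ Foxp3+ cells would remove epithelial cells.

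Ighm was high in all 4 Eos+ Treg libraries (1330 to 1660 CPM), although the sort was for CD4+ Foxp3+ cells, which a complete sort would free of B cells. In the first test its log2 ratio between the libraries with the least and the most B cell marker, -0.09, against -1.59 (SD 1.71) for the markers, was too close to their spread to decide. In the 6 pairs above its log2 ratio was 1.96 to 3, but Cd79b (1.28 to 2.72) and Ighd (1.31 to 3.44) moved by about as much, and Ighm lay above all 11 other B cell markers in only 3 of the pairs. A contribution of B cells to Ighm and the other B cell markers was left open. Of the 15 measured B cell markers, 3 exceeded 5 CPM in all 3 groups and 0 stood in another list.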

How the results depend on the processing

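The fits without the libraries numbered 1, without those numbered 1 and 2, and with the block and an estimated correlation together were chosen only after the data were seen. No called gene reversed its sign in any setting. The replicate block gave 3498, 5571 and 3300 changed genes, in the order of the report, and 2446 of 2500, 4581 of 4655 and 2211 of 2249 genes kept their call. It changed no list call other than those given in the report.

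Counts that moved by over 1.5 times were these, and apart from the stricter test and the fewer libraries the cause was not tested. The test against a 1.5-fold change gave 778 (630 higher, 148 lower), 1854 (1342, 512) and 513 (403, 110), with 421 shared. Without the 6 libraries numbered 1 and 2, which leaves 2 per group, there were 972 (718, 254), 2352 (1523, 829) and 1401 (799, 602), with 904 shared, and without number 1 alone 2294, 4127 and 2410. Lower genes of Eos- Tregs against Tconv numbered 1634 with library weights in limma-voom, 1564 with the replicate block, and 549 to 1338 with 1 library left out. Splitting the Tconv libraries gave a median of 883.5 shared genes.

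The genes named in the text understate how often a call is lost. Of all called genes of the rule, 9 of 93, 12 of 106 and 22 of 82 lost their call when some library was left out, against 1, 0 and 1 of those named. Under the 1.5-fold test 22, 20 and 36 of them were lost, and under any alternative 26, 23 and 38. Of 180 label checks under alternatives 173 kept their side of the threshold and 7 did not, all for Cxcr4. With an estimated correlation 0 of 48 list calls held, with or without the block. With fry 13 of 18, 13 of 15 and 10 of 15 held. Recovery of simulated 1.5-fold changes was 20.9% to 29.9%, with only 66 or 67 changed genes per fold. In the data 14.6% to 30.3% of genes were called, which makes the adjusted threshold less strict. How often such changes were missed in the data was not measured, so a missed threshold does not show that a gene was unchanged.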

Other observations

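The split counts of changed genes were already known when their bound was set, and the ranking of each list among the splits was chosen only after the list counts were seen; the bounds for the list counts and the shared genes were set beforehand.

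Some genes set Eos- Tregs apart from both other groups. Ntn4 was 20 ± 2.22 CPM in Eos- Tregs, 5.33 ± 2.68 in Eos+ Tregs and 0.394 ± 0.243 in Tconv (SD, n = 4). S1pr1 was also highest in Eos- Tregs, at 713 ± 50.8 CPM against 343 ± 75.2 in Eos+ Tregs. Il7r was lowest there, at 117 ± 79.4 CPM against 311 ± 112 in Eos+ Tregs (adjusted p = 0.0218) and 408 ± 89.1 in Tconv. Syp lies near Foxp3 on chromosome X and was 29.4 ± 7.58, 20.3 ± 3.83 and 0.835 ± 0.275 CPM in Eos+ Tregs, Eos- Tregs and Tconv.

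Transcripts of double-positive thymocytes followed the replicate number in part. Rag1 was 28, 35.6 and 26 CPM in the Eos+ Treg, Eos- Treg and Tconv libraries numbered 1, and 1.5, 0.0574 and 3.5 in those numbered 4. Dntt was 115, 106 and 105 CPM in those numbered 1. Tconv replicate 2 held the most Rag1, at 44.4 CPM. Ddx3y, on the Y chromosome, was 120 to 187 CPM in the libraries numbered 1 and 3 and 0 in the other 6.

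The splits cannot exclude chance for the counts of changed genes. Over all of them the pairing is ignored, and a split that mixes the sorted populations also widens the spread within its groups. Only the real split, 1 of the 35 splits of the 8 libraries, gave as many as 2500 genes in Eos+ against Eos- Tregs (highest other 100), 4655 in Eos+ Tregs against Tconv (highest other 0) and 2249 in Eos- Tregs against Tconv (highest other 1). The 7 other splits that part all 4 pairs gave 0 genes in each comparison, but with the real one they are too few for a share under 0.05. For the shared genes, 1 of 100 splits of the 12 libraries, the real one, gave 1674, with 1 as the highest other.

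For the number of lists called with the preset correlation, the splits do not exclude chance. They cannot decide it either way, since every other split that gave as many kept all but a single library of each group together. Eos+ against Eos- Tregs gave 18 lists, and 4 of 35 splits gave as many (highest other 19, median of the others 11). Eos+ Tregs against Tconv gave 15, as did 3 of 35 splits or more (highest other 17, median 8.5), and Eos- Tregs against Tconv gave 15, reached by 7 of 35 (highest other 20, median 8.5). Ranked list by list, the real split had the smallest p for 7 of 18, 9 of 15 and 4 of 15 called lists, among them the effector Treg list in Eos+ against Eos- Tregs and the Treg identity list against Tconv. The interferon-stimulated list in Eos+ against Eos- Tregs was matched by another split (2 of 35), and the cell cycle lists there by many (19 and 17 of 35).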
